A study of Homo sapiens with 3 samples.

How the data were processed

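The samples are 3 RNA-seq libraries of the MOLM-13 cell line, 1 each for untreated cells and for cells treated with FL-Fc-DM1 at 1 nM or 3 nM for 1 day. Per the labels' protocols, RNA was extracted with Trizol, mRNA was enriched with oligo(dT) beads, fragmented and copied to cDNA with random primers, and libraries were sequenced on an Illumina HiSeq instrument. The protocol does not mention a step that marks the strand. Per the submitters' processing notes, fastp 0.18.0, HISAT2, StringTie 1.3.1, DESeq2 and edgeR were used, with no role or order stated. The genome build, the annotation and the counting program are not given in the sources used here.

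The deposited table holds 20332 genes with an estimated read count and a TPM value per library. The deposited expected counts are not all whole: 12.4% of values in the control, 12.5% at 1 nM and 11.8% at 3 nM had decimals. The analysis had been planned for whole counts, so the estimated counts were rounded to whole numbers before use. The deposited TPM values are transcript levels scaled to the same sum in each library, per the file headers, and were used only as an alternative. The table names its libraries by the suffixes 0, 1 and 2, while the labels give untreated, 1 nM and 3 nM. The suffix 0 was read as untreated and 1 as 1 nM; 2 is no dose in the labels and was given to 3 nM because no other sample was left.

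Total counts were 19363034 in the control, 21146298 at 1 nM and 17752602 at 3 nM. The 10 most abundant genes took 8.80%, 8.69% and 8.43% of them. A floor of 50 reads in at least 1 of the 3 libraries left 10591 genes, of which 10531 are protein-coding in GENCODE release 29 (GRCh38). Gene locations were taken from that release by Ensembl identifier, which matched 20113 of the 20332 identifiers. It need not be the annotation behind the counts. Of the table's genes, 617 had no symbol, 99 of them measured, and these entered the counts of genes but were not named.

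Library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3; factors 1.02, 1.00 and 0.978 for control, 1 nM and 3 nM), and log2 CPM were computed with a prior count of 2. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each comparison is the difference of log2 CPM of 2 libraries. Genes were counted as higher or lower at 2-fold. As there is 1 library per condition, no test across libraries was possible. The counts of genes are descriptions by size alone, and the exact (Clopper-Pearson) 95% interval of a ratio of reads covers counting error only. A count of 3 reads corresponds to 0.152 CPM in the control, 0.141 CPM at 1 nM and 0.173 CPM at 3 nM.

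Before the data were examined, 28 gene lists with 582 entries were fixed, among them 5 lists of markers of other cell types. A few genes belong to more than 1 list. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of equal size drawn from the same 20 bins of mean log2 CPM. Members were counted as higher or lower at 1.5-fold. The percentile describes these libraries and is not a p-value, since genes of a list vary together.

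Named genes followed a rule fixed before the data were examined. For 3 nM against control the 10 highest and 10 lowest ratios were named, and 5 each for the other comparisons, among protein-coding genes outside chromosome Y with a symbol that is not a clone or locus name and at least 100 reads in at least 1 of the 2 libraries. For the comparisons with the control the other dose had to have the same sign. From each list that stood apart in either comparison with the control, the 3 members with the largest absolute log2 ratio at 3 nM were named among those with at least 100 reads in at least 1 of those 2 libraries, and 1 such member from each other list and from each marker list. FLT3 was always named. Not every gene that the rule picks is reported here. A few other genes are named in the text and marked as chosen after their values were seen.

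The scripts were tested on simulated data. For 3 nM against control, with 10591 genes, 97% of 200 genes changed 2.5-fold and 99.5% of 200 changed 4-fold passed 2-fold, as did 0.5% of 200 changed 1.5-fold and 1 of 10391 unchanged genes. These counts were Poisson draws without differences between cultures, so the rate among unchanged genes covers counting error only. Of 100 unchanged lists of 25 genes 8 stood apart, and of 100 lists shifted by 0.5 on the log2 scale all 100 did. The correlation of the comparisons with the control was set beside 100 simulated sets of unchanged libraries with Poisson counts.

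The alternatives were DESeq2 1.42.0 size factors, scaling by total reads, floors of 10 and 200 reads and no floor beyond 1 read, prior counts of 0.5 and 10, TPM with a pseudocount of 1, and protein-coding genes only. For lists they were also the mean in place of the median and random lists matched on gene length. After the data were seen, thinning of all libraries to the smallest total and a correction of log2 ratios for GC content and exon length were added. Counts of higher and lower genes at the higher dose against the control were also made with ratios centred at each level of mean expression. Pathway and process terms of the deposited annotation were ranked on ratios centred in the same way. That centring was not among the planned settings. Several columns of a sample were to be summed and counted as 1 replicate, which did not apply here. Reads were not analysed here.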

Results

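Polyadenylated RNA was sequenced from MOLM-13, an established human acute myeloid leukaemia line of monocytic type that carries an internal tandem duplication of the receptor tyrosine kinase FLT3. Cells were left untreated or exposed for 1 day to FL-Fc-DM1 at 1 nM or 3 nM. DM1 is a maytansinoid, a class of compounds that block the assembly of microtubules; the labels do not spell out the other parts of the name. There was 1 library for each of the 3 conditions, with 19363034 reads assigned to genes in the control, 21146298 at 1 nM and 17752602 at 3 nM. Of 20332 genes in the table, 10591 had at least 50 reads in at least 1 library and are called measured. The design allows 3 comparisons, each dose with the untreated library and the doses with each other, which ask how the transcriptome of the line differs after exposure and whether the difference depends on dose.

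With 1 library per condition no replicate error could be estimated and no difference has a replicate check, so every value describes these libraries and no p-value is given. Log2 ratios are of TMM-scaled reads per library size, given as CPM. Values given with TPM are ratios of TPM plus a pseudocount of 1, which draws ratios of low values towards 0. Intervals in brackets are exact 95% binomial intervals of the ratio of reads and cover counting error only. For each gene list, the median log2 ratio of its measured members was placed among 10000 random lists of the same size and mean expression, and a list is said to stand apart where its median lay outside their central 95%. The table names its libraries by the suffixes 0, 1 and 2. The suffix 0 was read as untreated and 1 as 1 nM, and 2 was given to 3 nM because it was the only sample left, so every statement on the 3 nM library rests on that reading.

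At 3 nM against the control, the median ratios of mitosis and chaperone genes lay above those of random lists, and those of DNA replication genes and of the progenitor programme lay below them. CDC20, the activator of the anaphase-promoting complex, had the highest ratio among genes named by the rule, which asks for at least 100 reads, at 4.03-fold the control (log2 2.01 [1.92, 2.11]; 1179 reads in the control, 4195 at 3 nM). CCNB1, which encodes the mitotic cyclin B1, was at 3.46-fold (1.79 [1.72, 1.86]). HSPA5, the main chaperone of the endoplasmic reticulum, was at 2.87-fold (1.52 [1.48, 1.56]). MAP2K6, a kinase that activates p38, had the lowest ratio among them, 13-fold below the control (-3.70 [-5.10, -2.98]; 157 reads in the control, 9 at 3 nM). Its size depended on the values used, with -1.43 from TPM and a pseudocount of 1. TPM was 2.691 in the control and 0.374 at 3 nM, low enough for the pseudocount to draw the ratio towards 0.

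In all, 107 of the 10591 measured genes were at least 2-fold higher at 3 nM and 215 at least 2-fold lower, while 85.9% lay within 1.5-fold. Ratios at 3 nM depended on expression level, with a median of -0.15 in the 2648 genes with the lowest mean expression and 0.08 in the 2647 with the highest, and with the ratios centred at each expression level 155 genes were higher and 123 lower. In GENCODE release 29 (GRCh38), CDC20 (ENSG00000117399) lies on chromosome 1 at 43358955 to 43363203, CCNB1 (ENSG00000134057) on chromosome 5 at 69167010 to 69178245, HSPA5 (ENSG00000044574) on chromosome 9 at 125234853 to 125241330 and MAP2K6 (ENSG00000108984) on chromosome 17 at 69414698 to 69553861. Other genes with the highest ratios were STON1, an endocytic adaptor (1.88), PIMREG, which is expressed in mitosis (1.79), RELB, a subunit of NF-kB (1.78), OLR1, a receptor for oxidised lipoprotein (1.74), APOE (1.69), MANF, a protein released on endoplasmic reticulum stress (1.61), the chemokine CXCL8 (1.61) and the readthrough gene RPS10-NUDT3 (1.60). Below MAP2K6, the lowest were SHISA2 (-2.86), FAM156A (-2.53), GABRA4, a subunit of the GABA-A receptor (-2.12), RUBCNL, a regulator of autophagy (-1.93), SKIDA1 (-1.89), YPEL1 (-1.85), ARHGAP11B (-1.72), PPP1R3G, a glycogen-targeting subunit of protein phosphatase 1 (-1.67), and NREP (-1.67). RPS10-NUDT3 shares exons with its parent genes, STON1 with the readthrough STON1-GTF2A1L, and FAM156A and ARHGAP11B have near-identical copies, so the counts of these genes are uncertain. With TPM and a pseudocount of 1 the ratios of FAM156A (-1.675) and GABRA4 (-1.31) were also more than 1.5 times nearer to 0, and YPEL1 (-0.55) was no longer past 2-fold. Their TPM values were low, at 7.95, 3.617 and 2.637 in the control and 1.803, 0.865 and 1.48 at 3 nM. The pseudocount draws such ratios towards 0, so these shifts do not by themselves show that TPM and counts differ. YPEL1 was within 2-fold in TPM itself.

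**Figure D1:**
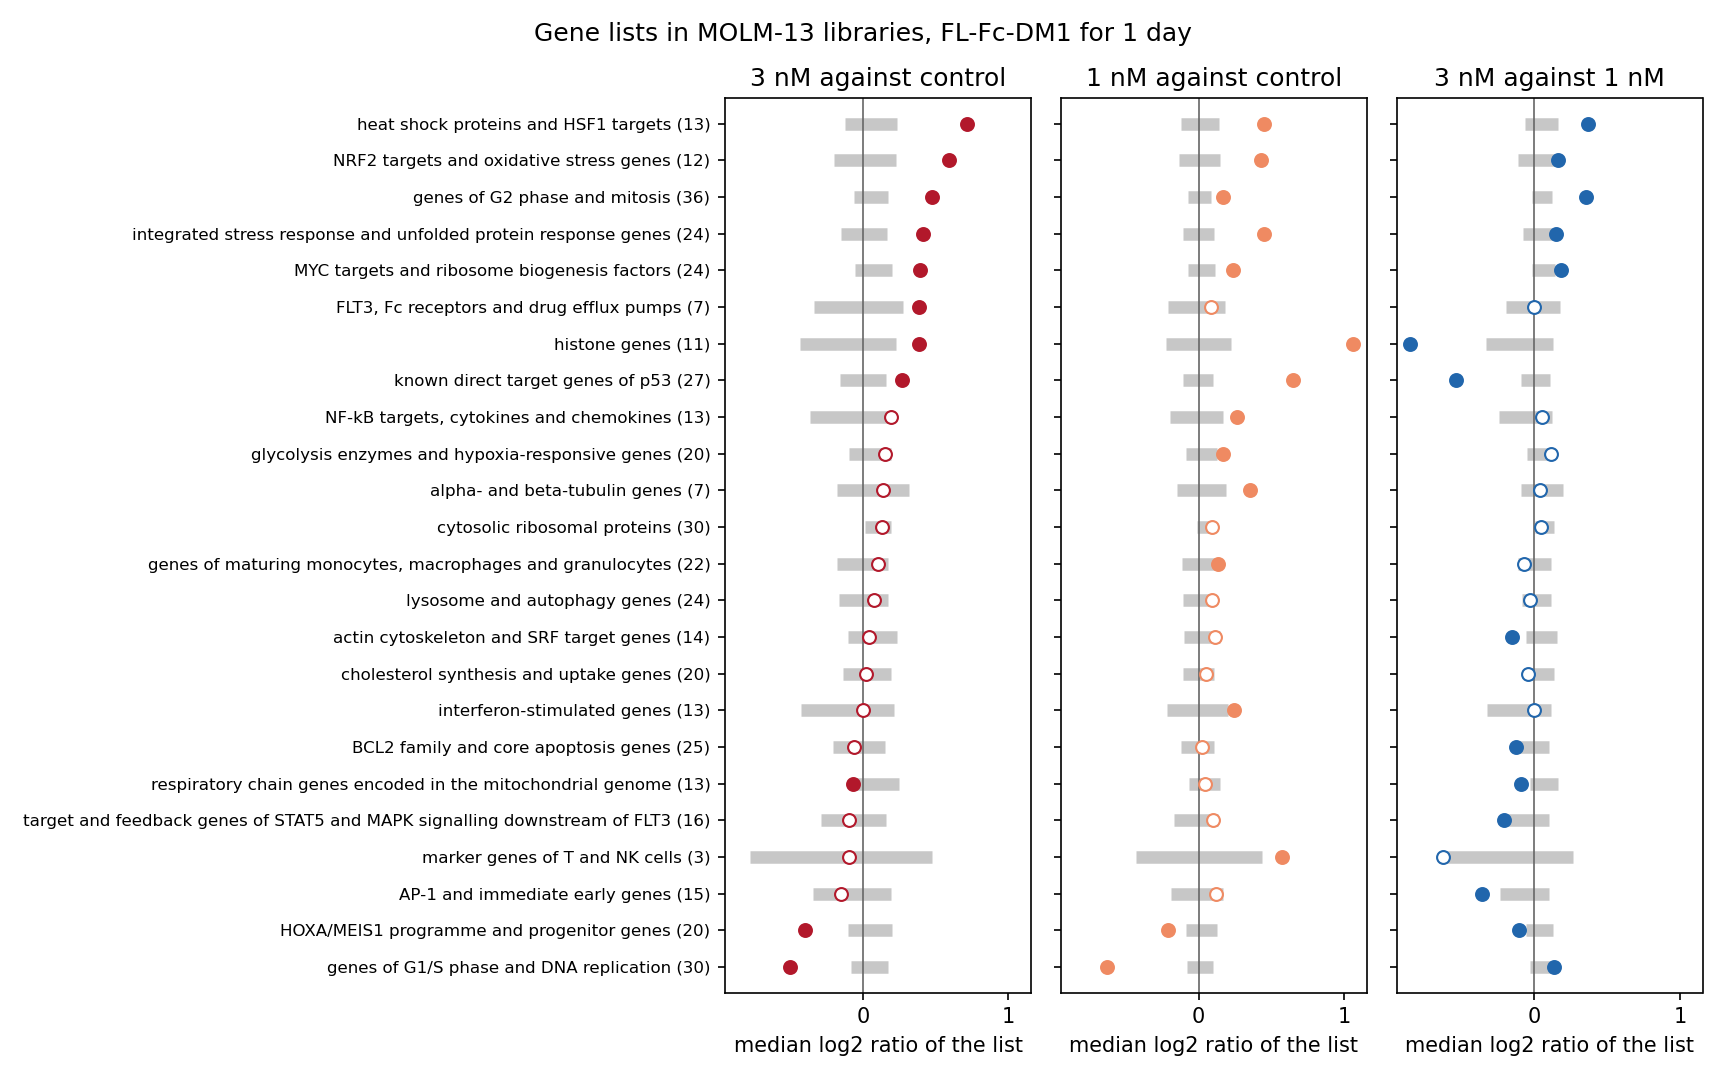
Median log2 ratio (x axis) of each gene list with at least 3 measured members (y axis, number measured in parentheses) in the 3 comparisons. Grey bars span the central 95% of 10000 expression-matched random lists; filled points stand apart from them and open points do not. Heat shock genes had the highest median at 3 nM (0.71) and replication genes the lowest (-0.50), while histone genes had the highest at 1 nM (1.06).

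Of the 36 measured genes of G2 phase and mitosis, 15 were at least 1.5-fold higher at 3 nM and 0 were that much lower. The median log2 ratio was 0.48, above all 10000 random lists, and 0.32 with TPM. Besides CDC20 and CCNB1, HMMR, a spindle-associated protein, was at 2.60-fold (1.38 [1.29, 1.47]). The list was not uniform: the kinases PLK1 (1.25) and AURKA (1.01) were higher, whereas TOP2A (-0.49), CDK1 (-0.40) and MKI67 (-0.02) were not, these 5 genes being chosen after their values were seen.

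Genes of G1/S phase and DNA replication moved the other way. The median of the 30 measured members was -0.50, below all random lists, with 13 at least 1.5-fold lower and 0 that much higher. HELLS, a chromatin remodeller of S phase, was 2.75-fold lower (-1.46 [-1.57, -1.35]), the transcription factor E2F1 2.25-fold lower (-1.17 [-1.39, -0.97]) and UNG, which removes uracil from DNA, 2.13-fold lower (-1.09 [-1.23, -0.95]).

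Chaperone and stress genes were higher at 3 nM in several lists. All 13 measured heat shock genes had ratios above 0, with a median of 0.71, and 7 were at least 1.5-fold higher, among them the co-chaperone BAG3 (1.21), HSPA8 (1.19) and HSPH1 (1.13). HSPA8 alone went from 1755 to 4006 CPM. Of 24 measured genes of the integrated stress and unfolded protein responses, 11 were at least 1.5-fold higher and 2 that much lower (median 0.42, above all random lists), led by SDF2L1 (1.54), HSPA5 (1.52) and CRELD2 (1.24), which all act in the endoplasmic reticulum. Of 12 measured NRF2 and oxidative stress genes, 7 were at least 1.5-fold higher (median 0.59), with SRXN1, which repairs oxidised peroxiredoxin, at 0.91, ME1 at 0.79 and the ferritin chain FTH1 at 0.61. Factors of ribosome biogenesis had a median of 0.40, with 6 of 24 at least 1.5-fold higher. Its named members were ODC1, the first enzyme of polyamine synthesis (1.03), the RNA helicase DDX21 (0.91) and RRP9 (0.87). These 4 lists lay above all random lists of their size.

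Genes of the HOXA and MEIS1 programme and of progenitor cells had a median of -0.39, below all random lists. Of the 20 measured, 7 were at least 1.5-fold lower and 0 that much higher. The transcription factors SOX4 (-1.10 [-1.27, -0.94]), HOXA3 (-0.99 [-1.49, -0.55]) and MEIS1 (-0.98 [-1.14, -0.83]) had the lowest ratios (HOXA3 -0.52 with TPM), while MYB (-0.04) and MYC (-0.03), chosen after their values were seen, were near the control. FLT3 itself (ENSG00000122025, chromosome 13, 28003274 to 28100592) was 1.45-fold lower (-0.53 [-0.58, -0.49]), at 481.2 CPM in the control and 332.6 CPM at 3 nM.

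Direct targets of p53 had a median of 0.27 at 3 nM (percentile 99.95), with 6 of 27 measured at least 1.5-fold higher and 1 that much lower; with TPM the median was 0.18. BTG2, an antiproliferative gene, was at 1.03, the cyclin-dependent kinase inhibitor CDKN1A at 0.72 and PHLDA3 at 0.72. The median of the 11 measured histone genes was 0.38 (percentile 99.86), with 2 at least 1.5-fold higher and 1 that much lower, but the list no longer stood apart with TPM (0.11) or with the mean in place of the median (0.08). Its named members were H2AJ (-0.65, or -0.41 with TPM), H3-3B (0.59) and H2AC6 (0.59). A list of FLT3, Fc receptors and drug efflux pumps stood apart (median 0.39), with 1 of 7 measured at least 1.5-fold higher and 0 that much lower. The efflux pump ABCC4 was at 0.39 and FCGR2B at 0.71, while 3 members, FLT3 among them, lay below 0. This list did not stand apart with a floor of 10 or 200 reads or with the mean (0.17 in each). The 13 respiratory chain genes of the mitochondrial genome had a median of -0.07, below random lists (percentile 1.43), with MT-ND6 at -0.50, MT-ND4L at -0.21 and MT-ND5 at -0.14. The list did not stand apart from random lists matched on gene length, and its median ranged from -0.06 with DESeq2 size factors to -0.23 after correction for GC content and exon length. Mitochondrial genes held 5.84% of reads in the control, 5.81% at 1 nM and 5.40% at 3 nM.

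Tubulin genes, which encode the protein that maytansinoids bind, went both ways and the list did not stand apart (median 0.14, 7 measured). TUBA4A (0.73 [0.59, 0.89]), TUBB6 (0.72 [0.60, 0.85]) and TUBB4B (0.62 [0.56, 0.69]) were at least 1.5-fold higher. TUBB, the most abundant of them and chosen after its values were seen, was lower at both doses (-0.46 at 1 nM, -0.55 at 3 nM). These 4 genes had the same directions with DESeq2 size factors, total reads and TPM, but TUBB6 (0.54) and TUBB4B (0.53) were below 1.5-fold with TPM and TUBB4B (0.57) with total reads. Tubulin genes are alike in sequence and could share reads.

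At 3 nM 11 further lists did not stand apart. NF-kB targets had a median of 0.19 (percentile 96.42), with 4 of 13 at least 1.5-fold higher, RELB, CXCL8 and NFKB2 (1.13) among them, and the list stood apart as higher with a floor of 10 reads (0.26), no floor (0.19), protein-coding genes only (0.22) or the mean (0.45). Interferon-stimulated genes had a median of 0.00 and went both ways, with 2 of 13 at least 1.5-fold higher and 1 that much lower. STAT2 was at -0.73, RIGI at -0.54 and MX2 at -0.51 (-0.84 with TPM), whereas IFIT2 (2.20; 16 reads in the control, 71 at 3 nM) and IFIT3 (2.08; 18 and 73 reads), chosen after their values were seen, were higher, at 1.09 and 1.22 with TPM. The interferon list stood apart as higher with a floor of 10 reads (0.27), no floor (0.29) or the mean (0.29). Glycolysis and hypoxia genes had a median of 0.15, and its members went both ways (ALDOC -0.68, PFKP 0.65, SLC2A3 -0.47); it stood apart as higher after correction for GC content and exon length (0.17). For genes of maturing myeloid cells the median was 0.11, with lysozyme LYZ at 0.61, NCF1 at 0.54 and MPEG1 at -0.69; it stood apart as higher with no floor (0.28). The medians were -0.06 for BCL2 family and apoptosis genes (BCL2L11, the pro-apoptotic BIM, -0.91), -0.09 for STAT5 and MAPK targets downstream of FLT3 (CCND2, cyclin D2, -1.24) and -0.15 for AP-1 and immediate early genes (IER3 1.38), which stood apart as lower with a floor of 200 reads (-0.37). They were 0.02 for cholesterol genes (STARD4 -0.63), 0.13 for cytosolic ribosomal proteins (RPS15 0.44), 0.08 for lysosome and autophagy genes (MCOLN1 0.80), which stood apart with the mean (0.21), and 0.04 for actin and SRF targets (CNN2 -0.46). Scaling by total reads moved the median ratio of all genes at 3 nM by -0.06 and so put the interferon, cholesterol and actin medians below 0, with their percentiles nearly unchanged (72.64, 42.17 and 37.01, against 72.755, 42.17 and 36.86). With TPM these and the lysosome median were below 0. NCF1, FCGR2B, FTH1, RPS15, HSPA8 and H3-3B have close copies or pseudogenes elsewhere, so their counts are uncertain.

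Most markers of other cell types had fewer than 50 reads in all 3 libraries. None of the 10 megakaryocyte markers was measured. Of the erythroid, B and plasma cell, and stromal or endothelial lists 1 gene each was measured: EPOR at -0.53, IGKC at -0.88 and PECAM1 at 0.07 at 3 nM. EPOR had 287 reads in the control and IGKC 277, while PECAM1, which monocytes also express, had 3799 there (192.9 CPM). PECAM1 was at -0.01 with TPM. Of 10 T and NK cell markers 3 were measured, with a median of -0.10 at 3 nM and NKG7 at -0.10 (477 reads in the control).

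At 1 nM against the control, targets of p53 and histone genes stood out. CDKN1A, which encodes the cell cycle inhibitor p21, was at 3.55-fold the control (1.83 [1.75, 1.91]; 1505 reads in the control, 5774 at 1 nM), and TP53INP1, a p53-induced gene, was at 3.34-fold (1.74 [1.61, 1.88]). The core histone gene H2AC6 was at 3.83-fold (1.94 [1.67, 2.25]). Genes of DNA replication were lower, with HELLS 2.01-fold below the control (-1.01) and UNG 2.06-fold below it (-1.04).

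Fewer genes were past 2-fold at this dose: 79 higher and 37 lower of the 10591, with 94.5% within 1.5-fold. CDKN1A (ENSG00000124762) lies on chromosome 6 at 36676460 to 36687339 and H2AC6 (ENSG00000180573) on the same chromosome at 26124145 to 26139116. The readthrough gene INO80B-WBP1 was also among the highest (1.76, uncertain for the reason given for readthroughs). FAM156A (-2.16), GABRA4 (-1.49), MAP2K6 (-1.49), SDK2, a cell adhesion molecule (-1.47), and SHISA2 (-1.196) were the lowest, and all but SDK2 were also among the lowest at 3 nM. With TPM and a pseudocount of 1, FAM156A was at -1.25, and MAP2K6 (-0.72) and SDK2 (-0.91) were no longer past 2-fold. The pseudocount brought the last 2 under that bound. TPM itself fell more than 2-fold for MAP2K6 (2.691 in the control, 1.246 at 1 nM) and SDK2 (2.199 and 0.698).

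**Figure D2:**
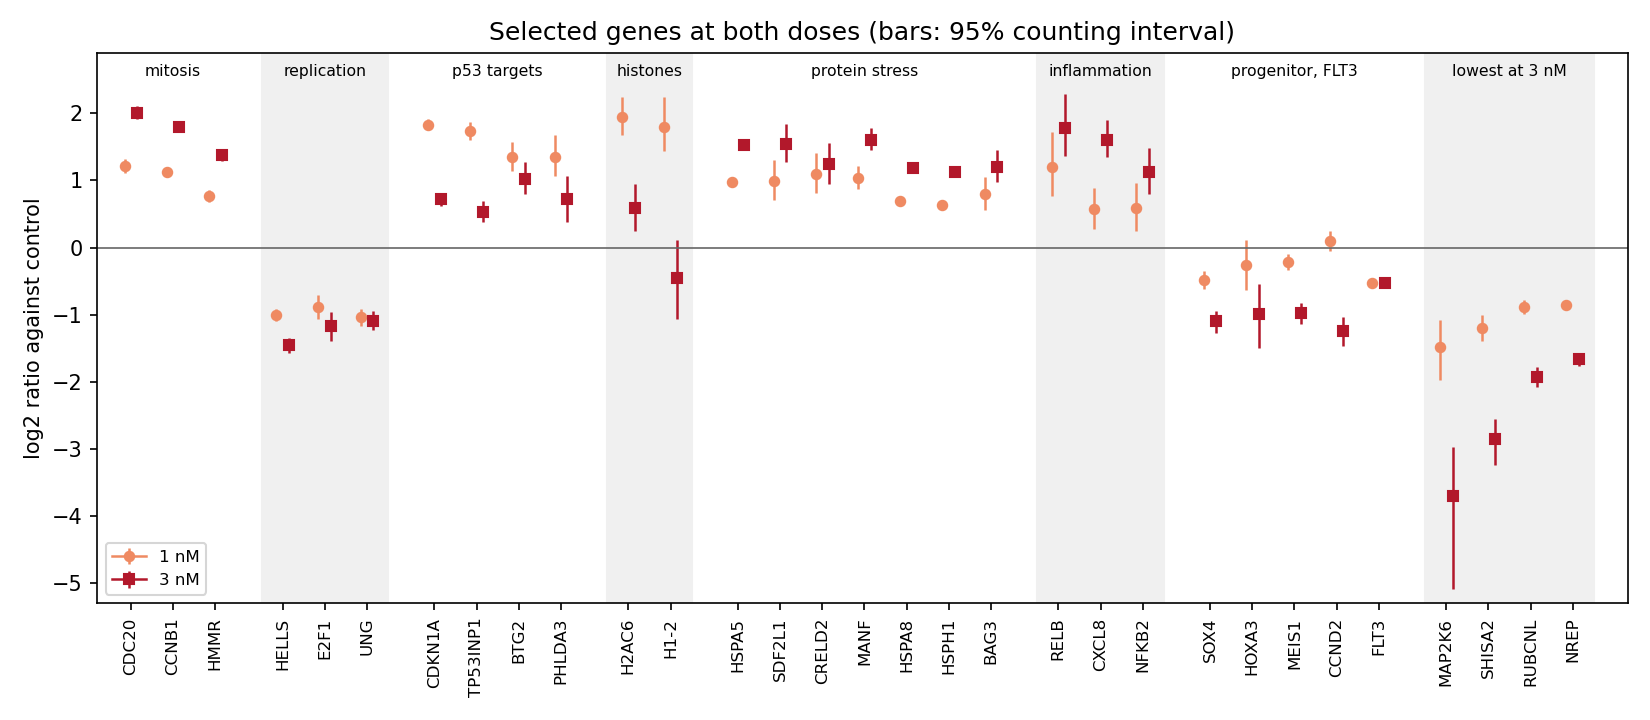
Log2 ratio against the control library (y axis) of selected named genes (x axis, grouped by function) at 1 nM (circles) and 3 nM (squares), 1 library per condition. Bars are exact 95% intervals of the ratio of reads and cover counting error only. CDKN1A was at 1.83 at 1 nM and 0.72 at 3 nM, whereas CDC20 was at 1.21 and 2.01.

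Of the 27 measured p53 targets, 16 were at least 1.5-fold higher at 1 nM and 0 that much lower, with a median of 0.65, above all random lists. BTG2 and PHLDA3 were both at 1.35. The histone median was 1.06, also above all random lists, with 6 of 11 at least 1.5-fold higher. H3-3B was at 0.46 and H2AJ at -0.04 (0.04 with TPM). Libraries made with oligo(dT) hold only the polyadenylated part of histone transcripts. T and NK cell markers had a median of 0.58 at this dose (percentile 98.93), from 3 genes of which NKG7 was at 0.19. They did not stand apart with no floor (0.27), with the mean (0.49) or after correction for GC content and exon length (0.39).

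Replication genes had a median of -0.63 with 18 of 30 at least 1.5-fold lower, E2F1 among them (-0.88), and the mitosis median was 0.17 with 8 of 36 at least 1.5-fold higher. With TPM the mitosis median was 0.0628, which still stood apart (percentile 98.64). CDC20 was at 1.21, CCNB1 at 1.13 and HMMR at 0.77. The heat shock median was 0.45 (BAG3 0.80, HSPA8 0.69, HSPH1 0.63), and that of the integrated stress and unfolded protein responses was 0.45 (CRELD2 1.10, SDF2L1 0.99, HSPA5 0.97). NRF2 targets had a median of 0.43 (FTH1 0.89, SRXN1 0.62, ME1 0.52), or 0.29 after correction for GC content and exon length, and ribosome biogenesis factors one of 0.24 (ODC1 0.75, RRP9 0.65, DDX21 0.51). Each of these 6 medians lay outside all 10000 random lists. The progenitor list had a median of -0.21 (percentile 0.01), with SOX4 at -0.48, HOXA3 at -0.26 and MEIS1 at -0.21, and FLT3 was at -0.53 [-0.58, -0.49].

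Other medians that stood apart at 1 nM were those of tubulins (0.35; TUBB6 0.40, TUBB4B 0.37, TUBA4A 0.35), NF-kB targets (0.27; RELB 1.203, NFKB2 0.59, CXCL8 0.57), interferon-stimulated genes (0.25; RIGI 0.58, STAT2 -0.21, MX2 -0.36), glycolysis and hypoxia genes (0.17; ALDOC 0.40, SLC2A3 0.32, PFKP 0.30) and myeloid maturation genes (0.13; NCF1 0.83, LYZ 0.27, MPEG1 -0.11). Of these, all but the NF-kB list, at 0.18 with TPM, lost that standing under at least 1 other setting. With TPM, RELB was at 0.75, no longer past 2-fold, and RIGI at 0.34. Of their members 0 of 7, 2 of 13, 3 of 13, 0 of 20 and 2 of 22 were at least 1.5-fold higher, in that order, and 0 that much lower. The lists that did not stand apart had medians of 0.08 for FLT3, Fc receptors and efflux pumps (FCGR2B 0.80, ABCC4 0.06, or -0.02 with TPM), 0.02 for apoptosis genes (BCL2L11 -0.53), 0.10 for STAT5 and MAPK targets (CCND2 0.10), 0.12 for AP-1 and immediate early genes (IER3 1.61) and 0.05 for cholesterol genes (STARD4 -0.15). For mitochondrial respiratory chain genes the median was 0.04 (MT-ND6 -0.10, MT-ND4L -0.16, MT-ND5 -0.18), for ribosomal proteins 0.09 (RPS15 0.20), for lysosome genes 0.09 (MCOLN1 0.16) and for actin and SRF targets 0.11 (CNN2 -0.13). AP-1, STAT5 and MAPK, lysosome and mitochondrial lists stood apart under at least 1 other setting, the last as lower (-0.12). EPOR was at -0.17, IGKC at -0.47 and PECAM1 at -0.08 (-0.30 with TPM).

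At 3 nM against 1 nM, a comparison that does not use the control library, the medians of p53 targets and histone genes lay below those of random lists and the medians of mitosis and heat shock genes above them. At least 1.5-fold differences were found for 12 of 27 p53 targets and 8 of 11 histone genes, all lower, but for 4 of 36 mitosis genes, all higher, and 0 of 13 heat shock genes. H1-2, a linker histone gene, was 4.78-fold lower (-2.26 [-2.81, -1.83]; 254 reads at 1 nM, 42 at 3 nM), and CDKN1A 2.16-fold lower (-1.11 [-1.18, -1.04]). CDC20 was at 1.74-fold (0.80 [0.73, 0.87]) and HSPA8 at 1.41-fold (0.50 [0.48, 0.52]). FLT3 did not differ between the doses within counting error (-0.00 [-0.05, 0.05]).

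At least 2-fold differences were found for 18 genes higher and 76 lower at 3 nM than at 1 nM, and 94.9% of the 10591 genes lay within 1.5-fold. The highest were OLR1 (1.35), the interleukin 7 receptor gene IL7R (1.195), RPS10-NUDT3 (1.18), and MGAT4A, a glycosyltransferase (1.12), followed by complement C3 (1.10). With TPM and a pseudocount of 1, MGAT4A (0.46), RPS10-NUDT3 (0.94) and C3 (0.94) were no longer past 2-fold. For RPS10-NUDT3 this came from the pseudocount, as TPM itself rose more than 2-fold, from 2.286 at 1 nM to 5.309 at 3 nM. Among the lowest after H1-2 were the glycosyltransferase MGAT3 (-1.97), SHISA2 (-1.67) and the readthrough PPT2-EGFL8 (-1.53, uncertain). MGAT3 was at -1.10 with TPM and a pseudocount of 1, from low TPM values of 2.064 at 1 nM and 0.429 at 3 nM. IL7R was at -0.07 at 1 nM against the control and at 1.13 at 3 nM.

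The p53 target median was -0.54 and the histone median -0.85, both below all random lists. Lower medians that stood apart were also found for AP-1 and immediate early genes (-0.36), STAT5 and MAPK targets (-0.21), actin and SRF targets (-0.15), apoptosis genes (-0.13), progenitor genes (-0.11) and mitochondrial respiratory chain genes (-0.09). In that order 3 of 15, 3 of 16, 1 of 14, 2 of 25, 5 of 20 and 0 of 13 members were at least 1.5-fold lower, and 0 that much higher. The progenitor value was -0.25 with the mean, and the actin median -0.04 with a floor of 200 reads. CCND2 was at -1.34 in this comparison. Higher medians that stood apart were those of heat shock genes (0.37), mitosis genes (0.36), ribosome biogenesis factors (0.19), NRF2 targets (0.16), genes of the integrated stress and unfolded protein responses (0.15) and replication genes (0.14). Few of their members differed by 1.5-fold: 0 of 24 ribosome biogenesis factors and 0 of 30 replication genes, 1 of 12 NRF2 targets, which was higher, and 3 of 24 stress response genes, which were lower. Of these lists, only those of heat shock, mitosis and ribosome biogenesis and of p53 targets, histones and AP-1 genes stood apart under every setting tried. The 3 measured T and NK cell markers had a median of -0.63, at the edge of random lists (percentile 2.5), and stood apart as lower in 5 other settings. C2H2 zinc finger genes, a class taken from the deposited annotation and not among the fixed lists, had a median of -0.20 in this comparison. The median of the replication genes thus lay below the control at both doses, and slightly higher at 3 nM than at 1 nM. Of the 30 members 25 were higher at 3 nM than at 1 nM and 5 lower, among the latter HELLS (-0.45), E2F1 (-0.29) and UNG (-0.05).

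**Figure D3:**
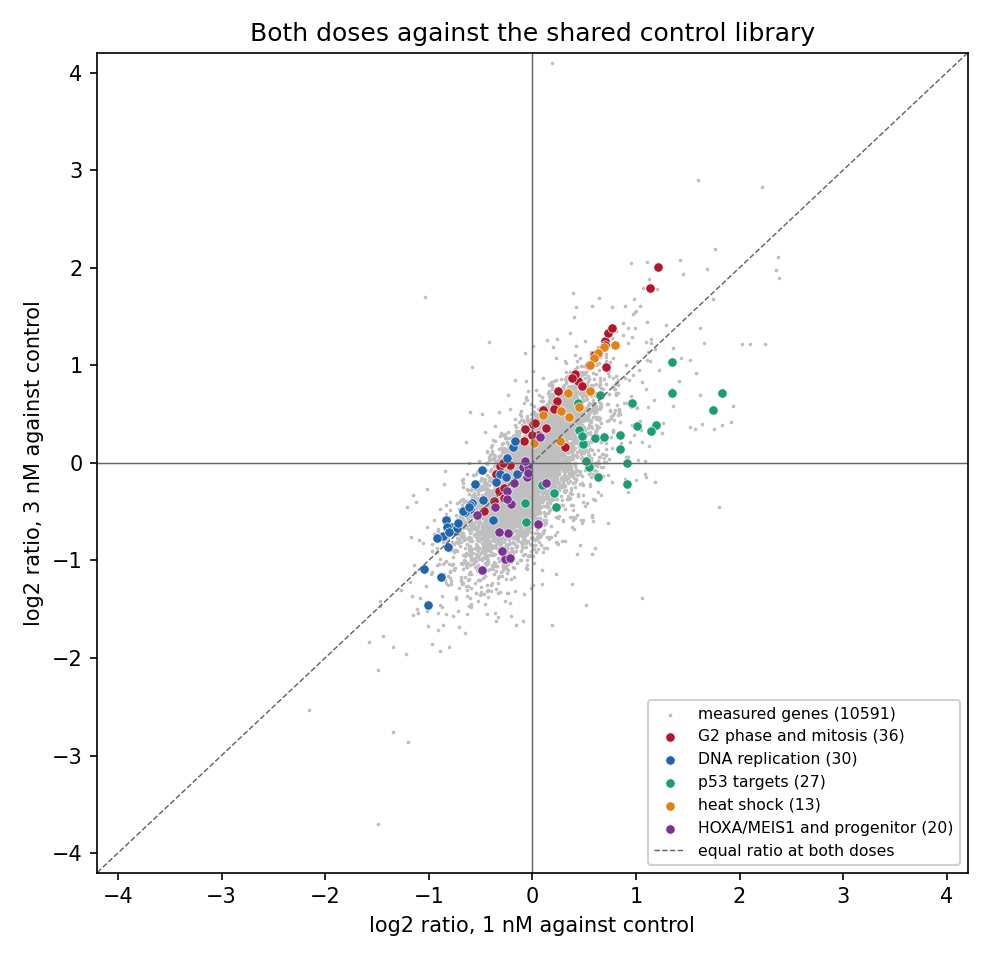
Log2 ratio at 1 nM (x axis) and 3 nM (y axis) against the same control library for measured genes, with members of 5 gene lists in colour; 6 of the 10591 genes lie outside the axes. Mitosis and heat shock genes with high ratios lie mostly above the dashed line of equal ratios, and p53 targets lie mostly below it.

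Across the 10591 genes, the log2 ratios at 1 nM and 3 nM had a Pearson correlation of 0.71, with genes not being independent replicates. Because both used the same control library, unchanged libraries simulated at these depths gave a correlation of 0.49. The covariance was 0.0990 against 0.00649 simulated, a difference of 0.0925. At both doses 39 genes were at least 2-fold higher, against 0.05 in the simulation and 0.80 for independent lists, and 27 were at least 2-fold lower, against 0 and 0.75. The simulation holds counting error only and independent lists leave out the shared control, so with 1 control library part or all of the excess may come from that library. Of the 215 genes at least 2-fold lower at 3 nM, 211 had a lower ratio at 3 nM than at 1 nM, and of the 107 at least 2-fold higher, 89 had a higher one. Of the 79 genes at least 2-fold higher at 1 nM, 21 had a higher ratio at 3 nM, and of the 37 at least 2-fold lower, 23 had a lower one. Genes picked for a large ratio at either dose tend to have a smaller one at the other by chance, so these counts do not by themselves order the doses.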

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

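The settings were fixed before the data were examined, except the thinning of all libraries to the smallest total and the correction for GC content and exon length, which were added after the data were seen. The centring of ratios at each expression level was not among the planned settings either. It was used for the counts of genes past 2-fold at 3 nM and to rank the annotation terms below. With 1 library per condition no library could be left out. No paired analysis was possible because each condition has 1 library. Counts of genes past 2-fold depended on the floor, which also sets how many genes are counted. In the order 3 nM against control, 1 nM against control and 3 nM against 1 nM, genes higher and lower were 249 and 430, 264 and 128, and 88 and 273 with a floor of 10 reads. They were 51 and 109, 27 and 18, and 4 and 17 with a floor of 200 reads, and 487 and 652, 466 and 289, and 297 and 516 with no floor beyond 1 read. With a prior count of 10 the genes lower at 3 nM than at 1 nM were 49. With TPM, 50 genes were higher at 3 nM and 39 at 1 nM against the control, and 9 higher and 29 lower at 3 nM against 1 nM. The pseudocount of 1 used with TPM draws ratios of low values towards 0, and how much of these changes it accounts for was not tested. The other 43 of the 66 counts stayed within 1.5 times the reported ones. The correlation of the comparisons with the control was 0.65 with a floor of 10 reads, 0.79 with 200 and 0.59 with no floor beyond 1 read, and in the other 6 settings stayed between 0.696 and 0.735. Of 40 list medians that stood apart, 24 did so in every setting, and 489 of 518 values stood apart in the same direction, with 0 reversed. For the rest the cause was not tested. Of 32 list medians that did not stand apart, 17 never did; of 412 values 28 came to stand apart in the reported direction and 3 with the other sign, and the cause of this was not tested either. With a floor of 10 reads these were AP-1 genes at 1 nM (0.195), NF-kB (0.2579) and interferon (0.2739) genes at 3 nM, and, between the doses, interferon genes (0.1468, sign changed) and T and NK markers (-0.63). With 200 reads they were AP-1 genes at 3 nM (-0.3717) and myeloid genes between the doses (-0.0887). With no floor beyond 1 read they were myeloid (0.2758), NF-kB (0.1905) and interferon (0.2886) genes at 3 nM, STAT5 and MAPK (0.1912) and AP-1 (0.195) genes at 1 nM and interferon genes between the doses (0.1686, sign changed). T and NK markers between the doses came to stand apart with a prior count of 10 (-0.6057), TPM (-0.626), the mean (-0.6835) and gene length matching (-0.63), AP-1 genes at 1 nM with TPM (0.0854), and NF-kB genes at 3 nM with protein-coding genes only (0.2242). With means they were NF-kB (0.4478), interferon (0.2885) and lysosome (0.2062) genes at 3 nM, STAT5 and MAPK (0.257), AP-1 (0.3751) and lysosome (0.2257) genes at 1 nM, and NF-kB (0.1086) and cholesterol (-0.0847) genes between the doses. After correction for GC content and exon length they were glycolysis genes at 3 nM (0.1734), mitochondrial genes at 1 nM (-0.1208, sign changed) and cholesterol genes between the doses (-0.0831), and after thinning the last again (-0.0721). With a floor of 10 reads the apoptosis median of 3 nM against 1 nM was -0.13, that of NRF2 targets 0.15, and that of FLT3, Fc receptors and efflux pumps at 3 nM 0.17. With 200 reads the last were again 0.15 and 0.17, and at 1 nM myeloid genes were at 0.12 and interferon genes at 0.0398. With no floor beyond 1 read, tubulins (0.20) and T and NK markers (0.27) at 1 nM no longer stood apart, nor did apoptosis (-0.13), STAT5 and MAPK (-0.21) and NRF2 (0.15) genes between the doses. With TPM the replication median between the doses was 0.10, that of glycolysis genes at 1 nM 0.0611 and that of histones at 3 nM 0.11. Means in place of medians were 0.15 for tubulins, 0.10 for glycolysis genes and 0.49 for T and NK markers at 1 nM, 0.0777 for histones and 0.17 for FLT3, Fc receptors and efflux pumps at 3 nM, and -0.15 for apoptosis and 0.0667 for stress response genes between the doses. Against random lists matched on gene length, the myeloid median at 1 nM (0.13), the mitochondrial medians at 3 nM (-0.0699) and between the doses (-0.0891), and the progenitor (-0.11) and actin (-0.15) medians between the doses no longer stood apart. After correction for GC content and exon length, interferon genes (0.15) and T and NK markers (0.39) at 1 nM no longer did. Of 2694 values of named genes under other settings, 2563 stayed within their counting interval, 130 moved beyond it and 1 whose interval excluded 0 changed sign, PECAM1 at 3 nM with TPM (-0.00695). Another 9 values, counted in those numbers, changed sign where the interval included 0, among them MGAT4A (-0.375), H2AJ (0.0377) and ABCC4 (-0.0159) at 1 nM with TPM. The shallowest library, at 17752602 reads, limits genes near the floor most, and a difference between conditions cannot be told from one between cultures.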

Other observations

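Among 1083 pathway and process terms of the deposited annotation with 20 to 200 measured genes, looked at after the lists above, several of the furthest from random sets concerned making, folding and degrading proteins. That distance was taken on ratios centred at each expression level, whereas the medians given here are not centred. The 1000 random sets per size were drawn from all measured genes, without matching on expression. Of the 43 measured proteasome genes, 14 were at least 1.5-fold higher at 3 nM and 0 that much lower, with a median log2 ratio of 0.50 at 3 nM and 0.29 at 1 nM. PSMD1 (0.81), PSMD3 (0.80) and PSMD14 (0.80) were among the 14. Genes of mitochondrial translation, which are nuclear genes, had a median of 0.25 over 93 genes at 3 nM. The 153 genes of rRNA processing were at 0.25 and the 136 of protein folding at 0.28, with 25 of the latter at least 1.5-fold higher and 4 that much lower.

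On the lower side, the 47 genes of the Fanconi anaemia pathway of DNA crosslink repair had a median of -0.28 at 3 nM and -0.24 at 1 nM, with 10 and 11 at least 1.5-fold lower and 0 that much higher. BRIP1 was at -1.05 at 3 nM and -1.14 at 1 nM, and FANCD2 was at -0.72 at both doses. Genes of potassium ion transport had a median of -0.40 at 3 nM over 40 genes, 12 of them at least 1.5-fold lower and 1 that much higher, among the lower ones the channel genes KCNC4 (-1.25) and KCNQ1 (-1.20). The genes of these paragraphs were chosen after their values were seen, and the terms share genes with each other and with the fixed lists. Ratios at 3 nM were lower in weakly expressed genes, so uncentred medians, such as that of potassium ion transport, may hold part of that trend.

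Of the tests weighed here, the pair that asks about the control library was chosen only after the result was seen, as was the rule that a value short of its bound by less than the spread of random medians decides nothing. The first pattern is that mitosis genes were higher and replication genes lower at 3 nM than in the control, and a trend with GC content and length as the whole cause is argued against, since after correction the mitosis median was 0.4496 and the replication median -0.5855, both outside all random lists. An unusual control library as the whole cause is argued against for the mitosis part, because the median of 3 nM against 1 nM, which leaves that library out, was 0.3559. The control library may still add to the mitosis ratios, and an unusual 1 nM or 3 nM library was not tested. For the replication part an unusual control library cannot be told apart from an effect of treatment, as the median of 3 nM against 1 nM was 0.1366. For fewer cells in S phase the prediction held: 104 genes annotated to DNA replication outside the lists had a median of -0.1006 (percentile 0.09 among random lists). This cannot decide the question, since an unusual control library, or fewer transcripts of these genes per cell, could lower them as well. They were read in the same 2 libraries, and cells in S phase were not counted. The median of these 104 genes was -0.1838 at 1 nM, below all random lists, and 0.0692 at 3 nM against 1 nM (percentile 96.55). For more cells in mitosis the prediction did not hold: 325 genes annotated to cell division outside the lists had a median of 0.04765 (percentile 87.76). This is below the bound of 0.0632, with 24 genes at least 1.5-fold higher and 21 that much lower. The shortfall is less than the spread of random medians. More cells in mitosis stays open only through the rule on such shortfalls, which was chosen after the result was seen. The same genes lay below random lists at 1 nM (-0.0377, percentile 0.355), where the mitosis list lay above them, and above random lists at 3 nM against 1 nM (0.0674, percentile 99.97).

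The second pattern is that p53 targets and histone genes were higher at 1 nM than at 3 nM. GC content and length as the whole cause is argued against by medians of 3 nM against 1 nM of -0.5757 for p53 targets and -0.8441 for histone genes after correction. Depth was weighed for p53 targets alone, whose median was -0.5355 with all libraries thinned to the smallest total. The ratios were already scaled by library size, so thinning could hardly have moved that median and decides little. A general loss of short-lived transcripts at 3 nM is a candidate explanation, as 407 C2H2 zinc finger genes outside the p53 list, a class known for short-lived transcripts, had a median of -0.1954 between the doses, below all random lists, with 43 at least 1.5-fold lower and 3 that much higher. Against the control, however, they lay below all random lists at 1 nM (-0.0911) as well as at 3 nM (-0.3098). The p53 targets (0.65 and 0.27) and histone genes (1.06 and 0.38) lay above random lists at both doses. The zinc finger median between the doses is also smaller in size than those of the p53 targets and histone genes. Transcript lifetimes were not measured, and dose itself stays open as a cause. A wrong reading of the library suffixes was not tested and would exchange the doses.

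The third pattern is that genes past 2-fold at 3 nM were more often lower than higher, 215 against 107. With all libraries thinned to the smallest total the ratio of lower to higher genes was 2.029, which weighs little on depth, since ratios were already scaled by library size. GC content and length are argued against by a ratio of 2.966 after correction. A trend with expression level cannot be told apart from other causes of the excess: removing it gave a ratio of 0.7935, from 155 higher and 123 lower genes, but this centres the ratios at each level and so largely sets the balance it measures. The median log2 ratio was -0.15, -0.06, 0.02 and 0.08 in 4 groups of about equal size from the lowest to the highest mean expression. Whether that trend came from the cells or from library preparation was not tested, as each condition has 1 library.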
